A study of Mus musculus with 4 samples.

How the data were processed

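Kidneys of 4 mice were dissociated, and libraries were made by the 10x Genomics droplet method, per the labels' protocols. The submitters' processing notes name Cell Ranger 7.1.0, Seurat and the mouse genome build mm10. The file used here is one matrix for the whole series. The authors deposited estimated counts: 0.404% of the entries above 0 were whole within 1e-06, 89.1% lay at most 0.1 below a whole number, and 46042 entries were stored as 0. A fractional subtraction of background from whole counts would leave such values, but this origin was not tested. The step that made them, the filters on cells and the way samples were joined are not given in the sources used here. Values were not scaled to depth.

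Groups were taken from the sample labels, with 2 control and 2 RARRES1 mice. The tests fixed before the data were examined were comparisons between these animals of counts summed per cell class, of shares of cells and of fixed gene lists. They need a map of cells to animals and names for the rows. Neither was used here, and nothing was inferred in their place from the order of columns or from values, so these tests were not run. The rule for named genes, which took the largest changes past an adjusted p of 0.05 together with fixed genes and list members, had nothing to act on, and the fixed markers were not applied. The analysis described instead was chosen after the matrix had been examined, apart from the minimum of 200 rows per cell, the Leiden resolution of 1.0 and the alternatives of 500 rows and resolution 2.0.

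Estimated counts were rounded to the nearest whole number. All 10247 cells had at least 200 rows. The planned limits on mitochondrial counts were not applied, since they need row names. Scrublet, run on the pooled cells because libraries were not mapped, marked 28 cells (0.273%). A share under 0.5% was taken as a caller that had not worked, so no cell was removed, contrary to the planned removal per animal. Doublets may therefore remain among the cells, since the submitters' filters on cells are not known here.

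Cells were clustered with scanpy 1.11.5 and python-igraph 0.11.9 on Python 3.11.15. Rows in at least 3 cells were scaled to 10000 counts per cell and log-transformed. The 2000 most variable rows were standardised with a cap of 10 and reduced to 30 principal components, and a graph of 15 neighbours was divided by the Leiden algorithm. No correction between libraries was applied. Families were formed by average linkage on 1 minus Pearson's r between cluster profiles, as log2(CPM + 1) over rows with at least 1000 counts. Families and their limit of r = 0.6 were introduced after the correlations between clusters had been seen and after cluster shares had proved to move with the settings. The limit of 10000 counts for deep clusters and the limits for restricted rows were also set after the matrix had been examined. Confidence intervals are exact (Clopper-Pearson) at 95%, from scipy 1.17.1.

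The shortfall of entries below whole numbers was profiled over the 1500 most often detected rows, of which 1477 had a value in each of 205 windows of 50 columns, using entries of at most 3 when rounded up. The first 3 principal components held 47.5, 9.18 and 6.155% of the spread of the profile. Each was then scaled to the same spread, and they were divided together by least squares at 3 change points. An earlier measure, the shortfall as a share of each cell's counts, misplaced the weakest step in simulated series. The components replaced it after they had been seen to separate the blocks, and 3 points were set because the study has 4 samples. For later steps, 50 columns on each side of a change point, 300 in all, were left out.

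The counts were tested on simulated data. Of 200 rows among 24043, each raised 8-fold in 1 of the simulated clusters, 200 were found restricted, with no other row called. Of 200 rows made 20-fold lower in 2 blocks, 200 were found. These simulations of rows were easier than the data. The simulated clusters were similar in size and shared the same profile apart from the raised rows, which had counts well above the minimum. Both changes exceeded the limits applied to the data, and the noise came from counting only. The results do not show how often rows of the data are missed or wrongly called. In 20 simulated sets of 205 windows, no change point was misplaced.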

Results

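Single-cell RNA sequencing was performed on kidneys of mice aged 18 months that had received doxycycline in their food for 16 months. Control littermates (2 mice, replicates 3 and 4) were set against 2 mice (replicates 5 and 6) carrying the transgenes Nphs1-rtTA and TRE-hRARRES1. Nphs1 encodes nephrin, a protein of the podocyte slit diaphragm, and its promoter drives a doxycycline-dependent activator in podocytes, the filtration cells of the glomerulus. The activator in turn switches on human RARRES1. The design asks how kidney cells of aging mice differ when podocytes overexpress this gene. The labels give the tissue as kidney cortex, whereas the extraction protocol describes dissociation of whole kidneys.

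The deposited matrix held estimated counts for 24043 rows in 10247 cells and totalled 187972643 counts. Rows and cells carry numbers alone in it, and neither gene names nor a map of cells to animals was used here. The comparison of RARRES1 mice with controls, the identity of cell types and the level of any gene, the transgene included, were therefore not analysed here. The pooled cells were treated as 1 sample, so the values have no replicate error, and the intervals given cover counting error only.

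A cell held a median of 12057 deposited counts, with an interquartile range of 4644 to 29472 and extremes of 487 and 191316. After rounding to whole numbers, a median of 3383 rows was detected per cell, from 202 to 10961. Of all rows, 20113 were detected in at least 10 cells, 9808 in at least 10% of the cells, and 169 in none. Counts were concentrated in few rows. The 10 rows with the most counts held 24.97% of all rounded counts, and the 100 rows with the most held 38.6%.

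The cells fell into 33 clusters, numbered by size. Cluster 1 held 11.8% of the cells (exact 95% binomial interval 11.2 to 12.5%), and the 10 largest clusters together held 65.1%. There were 9 clusters of under 100 cells, with 459 cells in all. The division into single clusters was not stable. Another random seed on the same counts gave an adjusted Rand index of 0.722 with the reported clusters. When each count was assigned at random to one of 2 equal parts and the parts were clustered separately, each gave 29 clusters, with an adjusted Rand index of 0.651 between them. Of the 33 clusters, 24 had a counterpart in the first part with a Jaccard index of at least 0.5. The share of the largest cluster also moved between 6.15% and 17.7% under other settings.

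**Figure D1:**
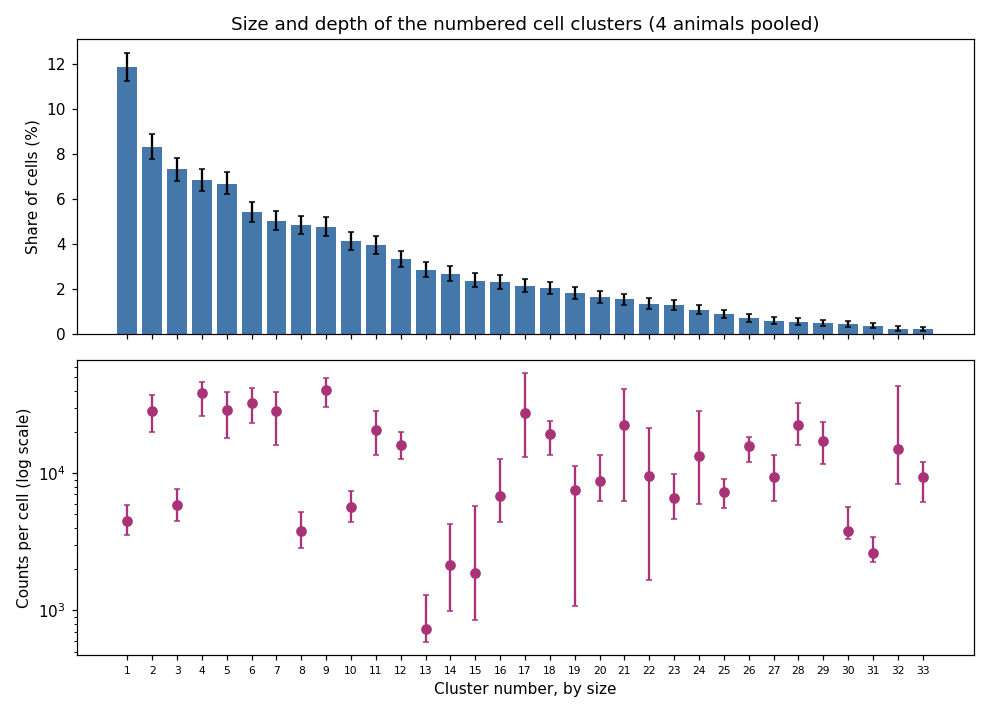
Share of the 10247 cells in each numbered cluster (upper panel, %, bars with exact 95% binomial intervals) and rounded counts per cell (lower panel, log scale, points are medians and lines the interquartile range). Cluster 1 held 11.8% of the cells, and cluster medians ran from 736 counts in cluster 13 to 40716 in cluster 9.

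Depth differed widely between clusters. Median rounded counts per cell ran from 736 in cluster 13 to 40716 in cluster 9, a ratio of 55.3. The 16 clusters with a median of at least 10000 counts contained 5441 cells, or 53.1% of the total (52.1 to 54.1%). The number of different rows detected at equal depth varied less. With every cell thinned to 1000 counts, which left out 478 shallower cells, cluster medians ran from 329 rows in cluster 12 to 757 rows in cluster 32. In cluster 12 the 10 rows with the most counts in the whole matrix took a median of 45.2% of each cell's counts, compared with 3.81% in cluster 25.

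Clusters were grouped into families by the correlation of their mean profiles across 10969 rows. With families set apart at an average r of 0.6, there were 4. Family A comprised 17 clusters and 57.9% of the cells (56.9 to 58.8%), family B 6 clusters and 21.8% (21.0 to 22.6%), and family C 9 clusters and 20.02% (19.2 to 20.8%). Family D was cluster 31 alone, with 38 cells (0.371%, 0.263 to 0.509%). Since families were formed from these correlations, a higher median r within families (0.741) than between them (0.505) was built in. The ranges overlapped: the lowest r within family A was 0.540, and the highest between a cluster of family A and one of family B was 0.744. These correlations are across rows, which are not independent replicates. The share of family A depended on the chosen r and was 41.5% at r of 0.7. Only 73.6% of its cells stayed together when families were formed again from the first part of the counts, compared with 99.96% for family B, 99.46% for family C and 100% for family D.

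**Figure D2:**
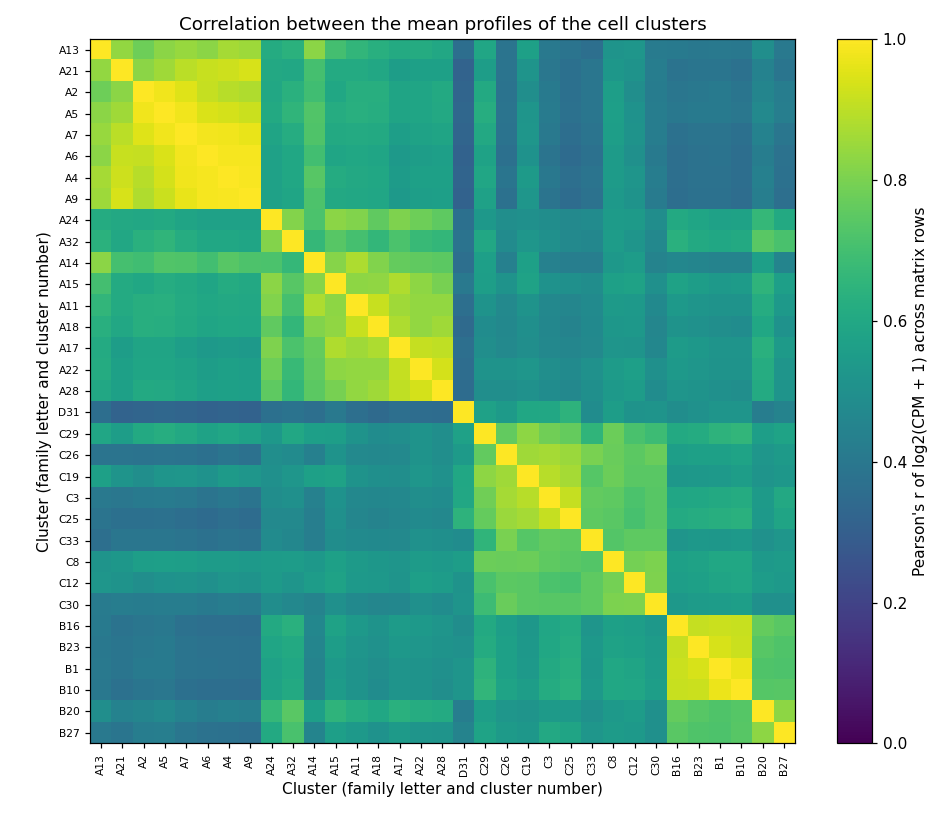
Pearson correlation (colour scale, 0 to 1) between the mean profiles of the 33 clusters, as log2(CPM + 1) over 10969 rows, with clusters labelled by family letter and number. Family A shows 2 separate squares of high correlation, and cluster 31 (family D) stands apart from family A.

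Depth and the share of counts in the 10 rows highest over the whole matrix were summarised for each family. The ranges of cluster medians in families A, B and C overlapped in both, and family D was a single cluster. Cells of family A held a median of 25338.5 counts, compared with 5243 in family B, 6229 in family C and 2626.5 in family D. The 10 rows took a median of 26.1% of a cell's counts in family A, 7.77% in family B, 7.57% in family C and 5.32% in family D. They were picked on counts summed over all cells, and family A had the most cells and the highest median depth, so its higher share was partly built in. Cluster medians of this share ran from 7.67 to 30.6% in family A, 6.76 to 12.3% in family B and 3.81 to 45.2% in family C, to which cluster 12 belonged. Cluster medians of depth ran from 736 to 40716 counts in family A, 4520 to 9327 in family B and 3785 to 17207 in family C. At 1000 counts per cell, the median number of rows was 576 in family A, 713 in family B, 619.5 in family C and 537 in family D.

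Rows restricted to one group of cells were counted in the part of the counts that had not been used for clustering. A row was called restricted when its CPM, its counts scaled to the total of the group, was at least 4 times that of every other group, with at least 30 counts. The groups were those formed from the first part. In all, 895 rows were restricted to 1 of the 29 clusters and 3338 to 1 of 5 families. The counterparts of families A, B, C and D had 871, 927, 711 and 123 such rows, that of family A holding 73.6% of its cells. The other of the 5 families, whose clusters matched clusters of family A, had the remaining rows. Because 30 counts were needed within a group, small or shallow groups required a higher CPM. The number of groups compared matters too, so these counts do not rank the families, or clusters against families. Of the 29 clusters, 13 had at least 20 restricted rows and 5 had none. The count over clusters changed with the limits, to 1829 at 2-fold, 516 at 8-fold and 450 at a minimum of 100 counts.

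The shortfall of the entries below the next whole number varied along the columns of the matrix. It came to a median of 0.965% of a cell's counts. Profiles of the shortfall, reduced to 3 components in windows of 50 columns, changed at 3 points. The median shortfall was 0.747% in the first block of columns and 0.920% in the second. In the third and the fourth it was 1.08% (interquartile range 0.975 to 1.145%) and 1.05% (0.956 to 1.12%), so that these differed in the components but little in the amount. These blocks were defined from the data, and none was assigned to an animal or a group.

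**Figure D3:**
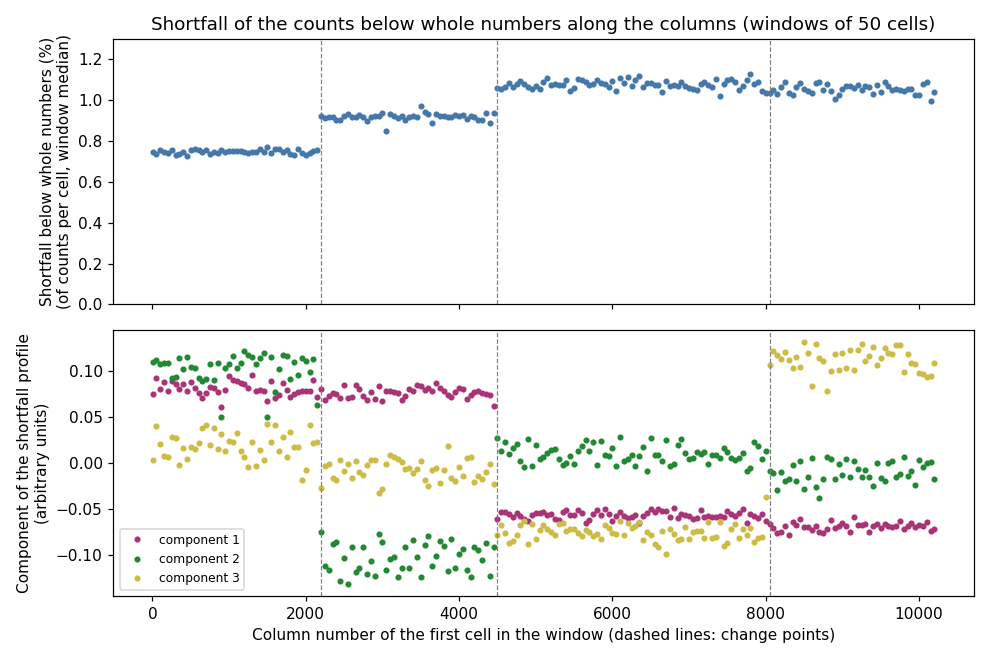
Median shortfall below whole numbers, as a percentage of a cell's counts (upper panel), and 3 components of the shortfall profile (lower panel, arbitrary units) for each window of 50 columns, against column number. Dashed lines mark the 3 change points, and the median shortfall was 0.747, 0.920, 1.08 and 1.05% in the successive blocks.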

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

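Apart from resolution 2.0 and the minimum of 500 rows per cell, the alternatives were chosen after seeing the data. The number of clusters stayed within 1.5 times 33 in 8 of 8 settings, a wide band, from 24 at resolution 0.5 to 46 at resolution 2.0. The share of the largest cluster left its 95% interval in 7 of 8, at 6.15% with resolution 2.0, 17.7% with resolution 0.5, 13.98% with another random seed, 8.495% with at least 500 rows, 13.95% with counts rounded up, 12.75% with 50 components and 12.7% with 4000 variable rows. That interval covers counting error only and served as a yardstick, not as a test of the settings. The largest cluster of another setting need not hold the same cells. The share in deep clusters moved to 55.0% at resolution 0.5, 58.0% with at least 500 rows and 51.4% with 4000 variable rows. Families depended on their limit: at r of 0.5 there were 2, with 42.15% in the second and 0% beyond these, and at r of 0.7 the largest held 41.5%. With at least 500 rows, the second family held 22.8%. That filter kept 9806 of the 10247 cells, so shares under it rest on a smaller total. The causes of the shifts were otherwise not tested. Adjusted Rand indices with the reported division were 0.624 to 0.771 for clusters and 0.709 to 0.9998 for families. No paired analysis was possible because the groups share no replicate number and cells were not mapped to animals. For the same reason the planned tests, scalings, count filters, leave-one-out runs, list tests, denominators by cell type and transgene check were not run. Clusters of low depth limit what restricted rows can show.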

Other observations

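Among the tests in this part, those of column order by depth, of separate correction, of other pairings of blocks and of low-depth clusters taken singly were chosen after the result was seen. The limits that define blocks and splitting rows were set after exploration with other limits.

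The profile of the shortfall below whole numbers stepped along the columns, with blocks at columns 1 to 2150, 2251 to 4450, 4551 to 8000 and 8101 to 10247. For the amount of the shortfall, a different mix of clusters was argued against. The spread of its block medians within clusters was 1.045 times the pooled spread (median of 21 clusters, 0.526 to 1.59). This ratio cannot speak to the step between columns 4551 to 8000 and 8101 to 10247, where the medians were close, at 1.08 and 1.05%. The components were not compared within clusters, so a different mix was not tested for the profile itself. An order by depth was argued against by a Spearman rho of 0.0496 between column number and counts. The 3 change points explained 97.8% of the spread of the 3 components, each scaled to the same spread. In 100 random orders of the windows they explained at most 7.51%. This shows an ordered pattern along the columns but cannot tell steps from other ordered patterns. A further point added 0.0569 percentage points. The components had been seen to separate the blocks, so little of their spread was left for it. Steps carried only by later components were left out, so the small gain cannot set the number of blocks. Libraries that were corrected separately and set end to end remain a hypothesis, since the components were chosen on the same data. Which animal a block holds, if it holds one, was not inferred.

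Some rows were detected at least 5 times as often in 2 blocks as in the other 2, and in at least 5% of the cells of the former. In the latter, detection ranged from 0 to 3.045% of cells, and 9 of the rows stayed under 1% in both. There were 14, with 6 higher in the first and second blocks and 8 higher in the others, and 0 under the other 2 pairings. The 3 possible pairings are too few to test the pairing itself, but chance differences in single rows were thus argued against. So was a different mix of clusters, since 100% of the rows kept a 3-fold ratio at equal cluster weights. These weights covered only the 21 clusters with at least 20 cells in every block. A different mix in the other clusters, or of cells within a cluster, was not tested. A subtraction that reached 0 was argued against as well, since stored zeros were 0 times as frequent as detection, provided that such zeros were stored. Whether genotype, sex, litter, strain background or library preparation separates the blocks stays open and untested, and no biological explanation was tested.

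The 2 rows with the largest ratio in each direction, chosen after their values were seen, were as follows in the 4 blocks in column order. Row 22295 was detected in 15.02, 15.27, 0.0290 and 0.0932% of cells, and row 18757 in 46.6, 68.3, 0.725 and 0.792%. Row 7820 was detected in 0 of 2150 and 0 of 2200 cells, and then in 20.03 and 22.2%. The counts of 0 allow up to 0.140 and 0.136%, an approximate limit of 3 divided by the number of cells, not an exact interval. Row 15170 was detected in 0.233, 0.273, 6.38 and 5.08%.

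Shares of the families per block are given as values only. Family A held 56.05, 56.95, 57.2 and 61.2% of the cells in the 4 blocks in column order, family B 20.1, 24.5, 21.6 and 21.0%, family C 23.6, 18.4, 20.6 and 17.6%, and family D 0.233, 0.182, 0.638 and 0.280%. Median counts per cell were 11492.5, 11299.5, 11562.5 and 14435. All 33 clusters had cells in each block.

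The median depth of 6 clusters, with 1390 cells, was under 4054.3 counts, the limit being the pooled median divided by 3. One candidate explanation is that they are shallow copies of deeper clusters without expression of their own. The test written before its result asked for under 5 restricted rows in every one of them if so, and at least 20 in every one if not. Over the 6 clusters it was undecided, with 0 to 83 rows. The same limits were then applied to each cluster, with rows counted in its closest match from the first part of the counts. Clusters 8 and 31 had 83 and 65 rows, above the limit of 20, which argues against shallow copies for these. Cluster 30, with 14 rows, lay between the limits and stays open. The closest matches of clusters 13, 14 and 15 had 1, 0 and 0 rows, at Jaccard indices of 0.5, 0.486 and 0.736. Such low numbers do not single out shallow copies. Of the 14 deep clusters formed from the same part of the counts, 4 also had under 5 rows, and 3 of them had 0. The minimum of 30 counts also asks for a higher CPM in shallow clusters. Few rows there need not mean a lack of expression of their own. Cluster 14 also had no counterpart at a Jaccard index of 0.5. No biological explanation was tested.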
